A study of Macaca mulatta with 16 samples.

How the data were processed

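Single-cell RNA libraries had been prepared from 4 male rhesus monkeys, 2 aged 7 years (young) and 2 aged 23 years (old). Each animal gave 4 samples, which makes 16 libraries. These were bone marrow cells, blood mononuclear cells from a Ficoll gradient, mechanically dissociated spleen, and a sample that the submitters call mesenteric lymph. Per the labels' protocols this last sample was white adipose tissue of the mesenteric lymph, minced and digested with collagenase, a step not described for the other 3 tissues. Libraries were made with 10x Genomics 3′ chemistry. Counting used Cell Ranger 6.0.1, per the file headers, and the submitters' processing notes name the Mmul_10 assembly and Seurat 4.0.3. The annotation release and whether intronic reads were counted are not given in the sources used here. The values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, deposited by the authors as matrices of called cells without normalization. Age group and tissue were taken from the labels and the animal from the sample titles, so the same 4 animals are present in each tissue and the replicate is the animal. Old replicate 1, old replicate 2, young replicate 1 and young replicate 2 are the same animals throughout.

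The matrices held 240457 barcodes, between 9643 and 22430 per library, and 21761 genes. Of these genes 16617 had a symbol in the files, 638 were named from the reference table of gene names and 4506 are given by identifier only. Cells with at least 500 UMIs, 300 to 6000 genes and at most 10% mitochondrial UMIs were kept (237681 cells). Doublets were then scored by the share of simulated doublets, each the sum of 2 random cells of the library, among 30 nearest neighbours on 1000 variable genes and 20 components. The highest-scoring cells were removed at 0.8% per 1000 cells, which took out 29909 cells (12.6%) and left 207772. In each of the 8 pairs of same-group libraries, gene totals correlated at 0.976 to 0.987 and differed by far more than sampling noise, with a chi-square per gene of 62.2 to 642. Over all pairs of the 16 libraries the lowest chi-square per gene was also 62.2, so no 2 libraries agreed within sampling noise.

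Clustering used 3000 randomly drawn cells per library with counts scaled to 10000 per cell and logged. It took 2000 variable genes without receptor segment, ribosomal, mitochondrial and unnamed genes, 30 principal components, 20 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). No batch integration was applied. The remaining cells joined clusters by a vote of their 15 nearest neighbours. This gave 33 clusters, and clustering the T-like cells again gave 23 sub-clusters. Clusters were named from marker lists written down before the data were examined. The name is the class with the highest mean z score of its markers across clusters. A cluster stayed unnamed with a best score under 0.5, fewer than 3 detected markers, or at least 2 of its 10 leading genes marking another class and more of them than mark its own. The same held for sub-clusters, which needed a score of 0.6. A cluster with a best score under 0.8 and a cycling score over 1 was called cycling, which applied to cluster 20. These thresholds were set after looking at the clusters. Cluster 20 held 0.304% of old and 0.119% of young marrow cells, 3.94% and 1.17% in lymph, 0.603% and 0.196% in blood, and 3.35% and 1.23% in spleen. Cluster 17 scored as NK-like, but 3 of its 10 leading genes were T-like and 2 NK-like markers, so it stayed unnamed and is compared by number. A name was compared only if no cluster under it had more leading markers of another class than of its own, which excluded the naive, CD4 and cytotoxic T-like names, whose sub-clusters are compared by number.

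For expression, counts were summed over the cells of a class in each library, and each class was tested where every library of the tissue had at least 50 such cells. Old and young were compared tissue by tissue with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood F-test) and Benjamini-Hochberg adjustment over genes, with a threshold of 0.05. Each tissue was compared with blood in a fit of 8 libraries with age group as a covariate. A difference of the age effect between tissues was tested as interaction terms with the animal as a block. Cell numbers were tested with the same edgeR test on cells per class, with the total as offset, for classes with at least 20 cells in a library. A permutation of 2 animals against 2 cannot go below a two-sided p of 0.333, so no permutation test is used for old against young. Because same-numbered libraries come from the same animal, as the titles give it, the animal pairs the tissues, and fits with the animal as a block were run beside those with age group. No pairing exists between old and young animals.

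Gene lists were fixed before the data were examined. They cover type I interferon response, inflammatory cytokines and NF-kB targets, immediate early genes, heat shock and chaperones, cytotoxic effectors, naive and central memory lymphocytes, T cell checkpoint and exhaustion, MHC class II presentation, S100, annexin and galectin genes, senescence and p53 targets, autophagy and lysosome, proliferation, age-associated and memory B cells, naive B cells, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. Another 17 lists hold cell type markers, which serve also as signs of RNA from other cells. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with the estimated correlation as the alternative. Members were also counted after adjustment over the list alone. Counts over several combinations of class and tissue take a member once for each combination where it passed. Named genes follow a rule set beforehand: adjusted p under 0.05, a symbol, a mean of at least 32 counts scaled to library size (CPM) and both old libraries on the same side of both young ones, up to 5 per direction with the largest change, plus up to 4 called members of each list that was called. Receptor segment genes were left out of that ranking, and some genes that the rule takes are not reported here. For cell shares and for counts of single genes, 95% exact intervals and floors of 3 counts cover counting error only.

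The test scripts were first run on simulated counts with the real means, library sizes and 200 changed genes, 1 simulation per comparison. For T-like cells of spleen (11571 genes), edgeR recovered 18% of genes changed 2-fold and 59% of those changed 4-fold, with 1 false call among 78; DESeq2 recovered 42% and 73% with 58 false among 173. For T-like cells of blood (12200 genes) edgeR recovered 12% and 72% with 2 false calls among 86, and DESeq2 34% and 79% with 105 false among 218; for monocyte/macrophage-like cells of blood (9406 genes) 26% and 87%. For NK-like cells of blood (8382 genes) it recovered 35% and 88%, and for B-like cells of lymph (10844 genes) 41% and 84%. For T-like cells of lymph against blood (12308 genes) the shares were 56% and 88%, for B-like cells of spleen against blood (10946 genes) 76% and 95%, and for the interaction in T-like cells (12997 genes) 27% and 76%. The interferon list raised 1.5-fold in simulated spleen T-like cells was called with the preset correlation (adjusted p = 1.01e-07, camera of limma) and not with the estimated one (adjusted p = 0.598), and none of 26 lists was called with no change. A class lowered 8-fold in simulated spleen cell numbers was not recovered (edgeR adjusted p = 0.9985).

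Alternatives were DESeq2 1.42.0, RLE size factors, no expression filter, all tissues in 1 fit, doublet-like cells kept, a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), resolution 2, thinning to equal depth, and leaving out each animal. Analyses ran in R 4.3.3 and Python 3.11.15 with scipy 1.17.1. Mast cell or basophil and epithelial or mesothelial marker lists had too few measured members for a test in any class.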

Results

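The data were single-cell RNA profiles of 4 immune tissues from male rhesus monkeys, 2 young animals aged 7 years and 2 old animals aged 23 years. Bone marrow, mesenteric lymph, blood and spleen of each animal gave 16 libraries, so each age group had n = 2 animals in each tissue. Total counts per library ran from 33054125 to 59949758 UMIs in marrow, 58694541 to 77552016 in lymph, 42175696 to 76487018 in blood and 49319138 to 76404478 in spleen. Between 8743 and 18369 cells per library were used. Their median depth was lowest in marrow, at 1162 to 2162 UMIs, and highest in blood, at 2706 to 3676.5 UMIs. The haemoglobin gene HBB took 13.29% of all UMIs in the marrow of old replicate 1. The labels name 2 comparisons, old against young animals within a tissue and the 4 tissues with each other.

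Each tissue held its own mixture of cells. The blood cells were mononuclear cells from a Ficoll gradient, so tissue and preparation cannot be told apart in shares set against blood. Granulocyte-like cells made up 52.7 ± 12.9% of marrow cells (SD, n = 4 animals) against 0.0259% of blood cells, B precursor-like cells 10.3 ± 7.89% against 0.0183%, and erythroid-like cells 5.59 ± 5.45% against 0.0127%. T-like cells were the largest class of blood, at 68.6 ± 18.7%, and fell to 14.5 ± 1.30% in marrow (log2 difference −2.25, edgeR adjusted p = 0.00103). Lymph had more plasma cell-like cells than blood (2.98 ± 2.11% against 0.413 ± 0.206%), more dendritic-like cells (2.52 ± 1.75% against 0.325 ± 0.228%) and fewer monocyte/macrophage-like cells (0.238 ± 0.158% against 6.38 ± 4.72%). Germinal centre B-like cells, the B cells that mutate and select their receptors in follicles, were 2485 of 64625 lymph cells and 3316 of 49671 spleen cells. None was found among 52680 blood cells, which allows a share of up to 0.005695%, so the pooled shares were at least 675-fold higher in lymph and at least 1172-fold higher in spleen (548-fold without young replicate 1 and 738-fold without young replicate 2).

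Of 14 groups tested against blood with edgeR, 13 classes and the unnamed cluster 17, 8 differed in marrow, 10 in lymph and 7 in spleen. The preparation of blood applies to all these differences as well. In marrow the B-like share fell (log2 −1.90, adjusted p = 0.0388), as did those of platelet-like cells (−2.04, 0.0229) and cluster 17 (−3.20, 0.00575), while the plasma cell-like share rose (1.67, 0.0388). In lymph the cycling-like share was 2.56% against 0.399% (log2 2.65, adjusted p = 0.00245), the NK-like share 0.7125% against 3.69% (−2.37, 0.00681) and that of cluster 17 0.0140% against 4.88% (−8.40, 5.43e-06). Stromal-like cells, 0 in blood, were at least 145-fold higher in lymph, and at least 46.3-fold without young replicate 2. No platelet-like or erythroid-like cell was found among 64625 lymph cells. The platelet-like share was at least 393-fold lower than in blood, and at least 142-fold without old replicate 1, while blood held only 7 erythroid-like cells. In spleen the cycling-like share was 2.29% (log2 2.56, adjusted p = 0.00302), the granulocyte-like share 0.317% (3.48, 0.01435), the dendritic-like share 1.01% (1.68, 0.0388) and the platelet-like share 0.152% (−3.32, 0.000972), and there the NK-like share was 10.97% (1.59, 0.04936) and that of cluster 17 1.07% (−2.18, 0.0388). Leaving out old replicate 1 or young replicate 2 lowered the marrow count to 5, while without young replicate 2 the spleen count was 3.

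**Figure D1:**
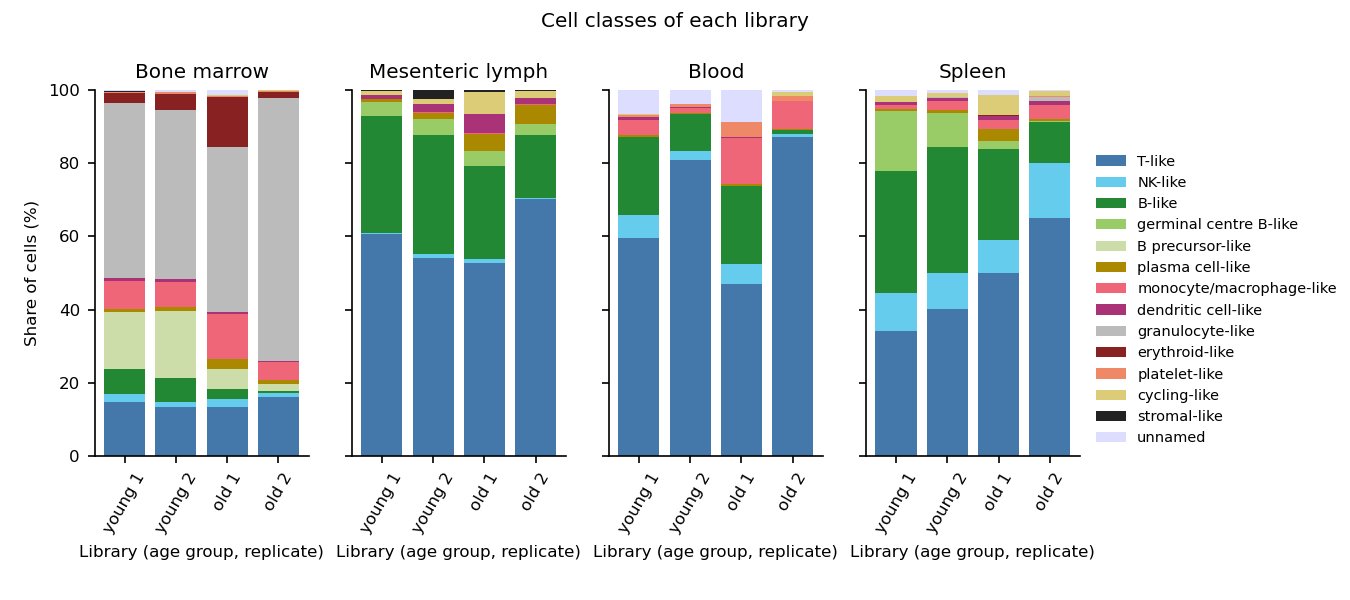
Share of cells (%, vertical axis, stacked to 100) in 13 named classes and the unnamed cluster 17 for each of the 16 libraries, grouped by tissue, with 1 bar per animal. Granulocyte-like cells fill 45.1 to 71.95% of the marrow bars and T-like cells 47 to 87.2% of the blood bars, and the germinal centre B-like band of spleen is 16.2 and 9.42% in the young animals and 2.06 and 0.327% in the old ones.

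The next comparison asked how the cell mixture differed with age. B lineage classes had the lowest p-values, but no class passed the test in any tissue. B precursor-like cells, which give rise to new B cells, were 3.65 ± 2.44% of old and 16.9 ± 1.99% of young marrow cells (SD, n = 2; log2 −2.21, SE 0.8405). Mature B-like cells were 1.70 ± 1.59% and 6.87 ± 0.133% of marrow, with a log2 difference of −2.01. In spleen, germinal centre B-like cells were 1.19 ± 1.23% in old and 12.8 ± 4.77% in young animals (log2 −3.42, SE 1.105), whereas in lymph they were 3.63 ± 0.618% and 4.10 ± 0.474%. Plasma cell-like cells, which secrete antibody, were 4.77 ± 0.390% of old and 1.19 ± 0.673% of young lymph cells (log2 2.00). Monocyte/macrophage-like cells were 9.93 ± 3.55% of old and 2.84 ± 1.97% of young blood cells, with an adjusted p of 0.573. edgeR called 0 of 42 class and tissue tests at an adjusted p under 0.05, cluster 17 included, 4 had an unadjusted p under 0.05, and these 4 shared an adjusted p of 0.411. In marrow 4 groups were called without old replicate 1 and 6 without old replicate 2, and in spleen 2 without old replicate 2.

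Within T-like cells, some sub-clusters were filled mostly by single animals, old or young. Of sub-cluster 8, led by SOX4 and SLC2A3, 77.2% came from the lymph of young replicate 1. Its cells were shallow, with a median of 996 UMIs and a ratio to library depth of 0.55. Of sub-cluster 3, which scored as cytotoxic T-like, 63.8% came from the blood of young replicate 2. In blood, sub-cluster 0, led by the naive T cell genes CCR7 and LEF1, held 30.3 and 3.77% of T-like cells in the old animals and 48.7 and 27.4% in the young ones. Sub-cluster 2, led by CX3CR1 and the cytotoxic genes PRF1 and GZMB, held 61.6% of blood and 47.7% of spleen T-like cells in old replicate 2, and at most 0.607% of either in the other 3 animals. Sub-cluster 14, led by CLEC12A, FCGR3 and PRF1, took 18.3% of blood T-like cells in old replicate 1 against at most 0.0418% elsewhere in blood. In spleen, 44.4% of the T-like cells of old replicate 1 lay in the unnamed sub-cluster 10, led by FCRL6, ITGAX, TYROBP and KIR3DH, and 99.8% of that sub-cluster came from this library. Of the spleen T-like cells of the other 3 animals, 0.0132 to 0.100% lay in it. Sub-cluster 3 went the other way. In blood it held 2.44 and 2.41% of T-like cells in the old animals against 18.5 and 47.85% in the young ones. In spleen the shares were 1.18 and 2.68% against 10.1 and 13.3%, and in marrow 0 and 0.212% against 9.58 and 19.0%. The edgeR adjusted p was 0.3005 in each of these tissues, and in lymph the shares of old and young animals overlapped. In marrow, unnamed sub-clusters held 98.5 and 52.3% of T-like cells in the old animals against 6.45 and 5.11% in the young ones. This left less room there for the other sub-clusters, sub-cluster 3 among them, in the old animals.

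In lymph, sub-cluster 11, led by CCL3, IFNG and GZMA, held 2.13 and 38.5% of T-like cells in the old animals against 0.027 and 0.200% in the young ones (log2 7.48, edgeR adjusted p = 0.0382), and 95.2% of it came from the lymph of old replicate 2. Sub-cluster 2 held 0.209 and 4.29% against 0 and 0.0250% (log2 7.46, adjusted p = 0.0382). These were the only calls among 59 sub-cluster tests, of which 9 had an unadjusted p under 0.05, and both ended whichever animal was left out: the adjusted p was 0.0516 for both without old replicate 1, 0.267 for sub-cluster 11 and 0.386 for sub-cluster 2 without old replicate 2, and 0.990 and 0.380 for both without young replicate 1 and young replicate 2. Among 87 tests of the main clusters, 2 were called, clusters 15 and 2 of lymph (log2 7.37 and 7.60, both adjusted p = 0.00896). Cluster 15 held 1.38 and 27.96% of lymph cells in the old animals against 0.0218 and 0.156% in the young ones, and 93.9% of it came from the lymph of old replicate 2; cluster 2 held 0.292 and 2.46% against 0 and 0.0136%. Both stayed called without old replicate 1 (adjusted p = 0.0254 and 0.0270) and neither did without old replicate 2 (0.254 and 0.204), young replicate 1 (0.425 for both) or young replicate 2 (0.0914 for both). Follicular helper T-like cells, which help germinal centre B cells and were led by CD200, IL21 and CXCR5, were 7.43% of old and 27.7% of young spleen T-like cells, with an adjusted p of 0.585, and 4.92 and 10.98% in lymph. GZMK T-like cells were 12.4 ± 0.0566% of old and 19.7 ± 0.976% of young spleen T-like cells (log2 −0.66, adjusted p = 0.186; with TMM factors log2 0.03 and adjusted p = 0.976). Regulatory T-like cells, led by IL2RA and CTLA4, were 4.89 and 3.22% in lymph (adjusted p = 0.751). In marrow most old T-like cells fell into sub-clusters led by HBB or granulocyte genes, and sub-cluster 0 held 0.147 and 2.12% of T-like cells in the old animals and 50.95 and 40.8% in the young ones (adjusted p = 0.345). Outside lymph, 5 sub-clusters of marrow, 2 of blood and 1 of spleen were called without old replicate 1, and 8, 1 and 1 without old replicate 2, while the main clusters called were 7, 1 and 6 and then 3, 0 and 1; without either young animal 0 were called.

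**Figure D2:**
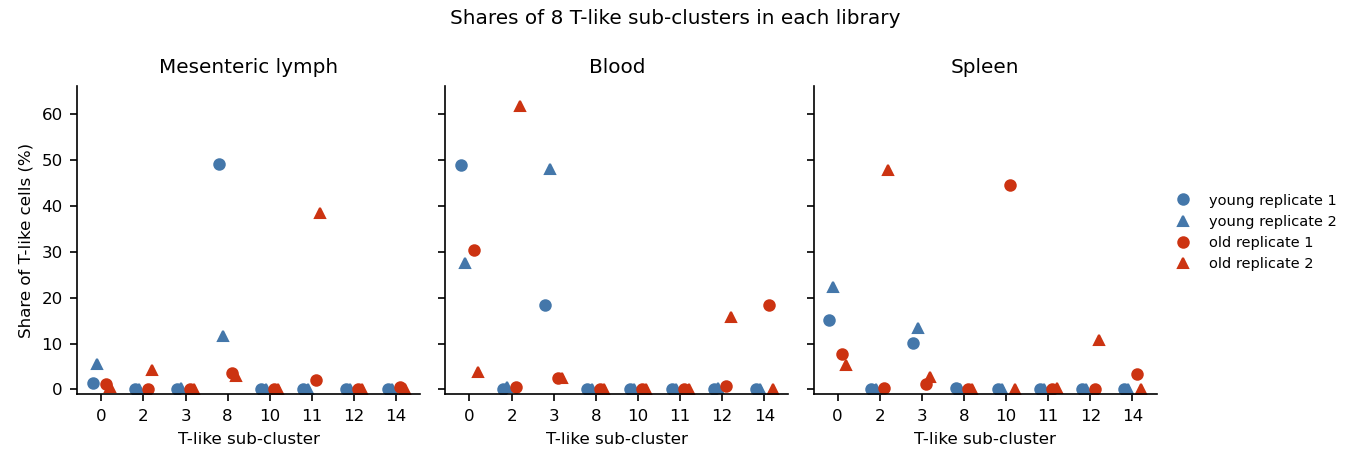
Share of T-like cells (%, vertical axis) in 8 sub-clusters (horizontal axis) in lymph, blood and spleen, with 1 point per animal, blue for young and red for old. Sub-cluster 2 reaches 61.6% in blood and 47.7% in spleen in old replicate 2, and sub-cluster 10 reaches 44.4% in the spleen of old replicate 1. Sub-cluster 8 reaches 48.97% in the lymph of young replicate 1, and sub-cluster 3 reaches 47.85% in the blood of young replicate 2.

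Across cell classes, genes induced by type I interferon were higher in the old animals and heat shock genes lower. PLSCR1, an interferon-induced scramblase, was higher in the old animals in all 14 combinations of class and tissue tested, with a median log2 difference of 2.03 (range 0.14 to 3.95), and after adjustment over the list alone it rose in 13 of them. IRF9, a transcription factor of the interferon response, was also higher in all 14 (median 0.65, range 0.15 to 1.03) and rose in 10 by this adjustment. In each of the 14 combinations for IRF9, and in 13 for PLSCR1, both old libraries lay above both young ones, an arrangement that chance gives in either direction for 0.333 of genes. IRF7 rose in 9 (median 1.21) and XAF1 in 8 (0.82). The antiviral genes ISG15 and MX2 rose in 6 and 5, with medians of 1.28 and 0.53. Not all members moved: RSAD2 (median 0.12) and SAMD9 (−0.09) passed in none, and IFI44 fell in 3 and rose in 1.

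As a list, the interferon genes rose in all 14 combinations (camera with the preset correlation). The median log2 difference was 0.34, 0.50, 0.43 and 0.31 in T-like cells of marrow, lymph, blood and spleen, 0.53, 0.94, 0.47 and 0.43 in B-like cells, 0.52, 0.55 and 0.44 in NK-like cells of marrow, blood and spleen, and 0.24, 0.64 and 0.23 in monocyte/macrophage-like cells of these 3 tissues. Adjusted p ran from 5.27e-17 in B-like cells of lymph to 0.01 in monocyte/macrophage-like cells of spleen. Like those of all list tests with the preset correlation, these p-values set the list's genes against all other genes as nearly independent. They do not measure the spread between animals. No call held with an estimated correlation, where the lowest adjusted p for this list was 0.449. Summed over the 14 combinations, which share the same animals, 10 calls of members were up and 1 down over all genes tested. When adjusted over the list alone, 108 such calls were up and 4 down. The same gene can count in several combinations. The list was called in 11 combinations without old replicate 1 and in 12 without young replicate 1, and in monocyte/macrophage-like cells of spleen its median without young replicate 1 was −0.29.

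**Figure D3:**
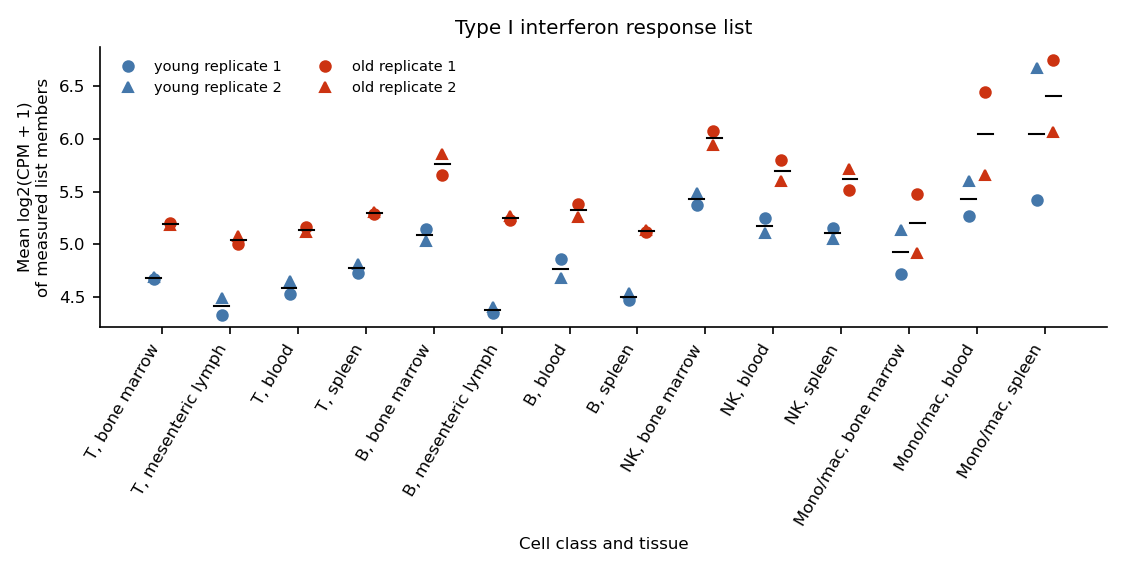
Mean log2(CPM + 1) of the measured type I interferon list members (vertical axis) in each class and tissue (horizontal axis), with 1 point per library and black bars for the group means. Both old libraries lie above both young ones in 12 of the 14 combinations, the exceptions being monocyte/macrophage-like cells of marrow and spleen.

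Heat shock and chaperone genes fell as a list in 13 of 14 combinations, all but NK-like cells of blood, with medians from −0.25 in NK-like cells of spleen (adjusted p = 0.0227) to −0.53 in monocyte/macrophage-like cells of spleen. FKBP4, a co-chaperone of HSP90, was lower in old animals in all 14 (median −0.80, range −1.54 to −0.57) and fell in 5 after adjustment over the list alone. CHORDC1 was also lower in all 14 (median −0.58) and fell in 4. STIP1, which links HSP70 and HSP90, had a median of −0.68, HSPH1 of −0.65, and HSPA1B of −0.82 over the 11 combinations where it was measured, while HSPA8 stood at 0.01. No member passed over all genes tested with edgeR. Summed over the combinations, 24 calls of members were down when adjusted over the list alone. No call of the list held with an estimated correlation (lowest adjusted p = 0.449). It was called in 6 combinations without old replicate 2 and in 9 without young replicate 2.

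Cytotoxic effector genes rose as a list in 10 of 14 combinations, among them all 4 tissues in T-like cells, with medians of 1.41 in marrow, 1.72 in lymph, 1.14 in blood and 1.63 in spleen, and B-like cells of spleen (0.99). Summed over the combinations, 53 calls of its members were up and 3 down when adjusted over the list alone. Over all genes tested 5 were up. Genes of naive and central memory lymphocytes fell in 8 combinations, in T-like cells by medians of −0.43, −0.37, −0.45 and −0.72 in marrow, lymph, blood and spleen. Calls of members of this list, summed in the same way, were 21 down and 2 up when adjusted over the list alone. Over all genes 5 were down. Without old replicate 2 the median of the list in T-like cells of blood was 0.04. Nuclear-encoded oxidative phosphorylation genes rose in 10 combinations with medians of 0.10 to 0.30, while no member passed over the list alone. Inflammatory and NF-kB genes rose in 5 combinations (17 member calls up over the list alone, 3 over all genes). S100, annexin and galectin genes rose in 6 and fell in 1 (21 member calls up and 1 down over the list alone, 0 over all genes). Autophagy and lysosome genes rose in 5 (1 member call up over the list alone). Checkpoint and exhaustion genes rose in T-like cells of blood (median 0.51) and monocyte/macrophage-like cells of marrow (0.96). Summed over the combinations, 13 member calls of this list were up and 4 down over the list alone, and 1 was up over all genes tested. None of the list calls given here held with an estimated correlation (camera, lowest adjusted p = 0.449).

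Cytosolic ribosomal protein genes went both ways, up in 3 combinations, led by B-like cells of spleen (median 0.32, adjusted p = 1.31e-12), and down in 7, led by T-like cells of marrow (−0.26). Several of these falls turned: the median was 0.06 in T-like cells of marrow and 0.27 in those of blood without old replicate 2, the latter called up (adjusted p = 8.67e-06), 0.03 in B-like cells of lymph without old replicate 1, 0.0671 and 0.14 in T-like cells of blood and spleen without clusters mostly of 1 library, called up in spleen (adjusted p = 0.00238), and 0.02 in NK-like cells of blood with cluster 17 counted among them. MHC class II genes, which present antigen, rose in B-like cells of blood (0.32) and spleen (0.30). Naive B cell genes fell in T-like cells of spleen (−0.80), B-like cells of lymph (−0.67) and NK-like cells of blood (−0.28) and spleen (−0.76), and age-associated and memory B cell genes rose in T-like (0.61) and B-like cells (0.49) of lymph and NK-like cells of marrow (0.94). Immediate early genes rose in T-like cells of lymph (0.27) and fell in NK-like cells of blood (−0.43), where BTG2 and MYC were called over all genes (log2 −1.28 and −1.12). Mitochondrially encoded genes were called up in monocyte/macrophage-like cells of marrow (adjusted p = 0.0221), where their median was 0.46 and their mean −0.04. Senescence and p53 target genes were called in none of 14. Summed over the combinations, 11 member calls were up and 6 down when adjusted over the list alone. Of the cell cycle inhibitors, CDKN2B was called in NK-like cells of blood (log2 3.29, edgeR adjusted p = 0.0325) and CDKN1A in no combination. Over all 342 list tests 100 were called up and 45 down, and 0 with an estimated correlation (lowest adjusted p = 0.449).

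Marker genes of other cell types moved with age inside the classes, and these shifts stand beside every gene group given here. Some lists share members, so their shifts are not separate evidence. KLRD1, NKG7 and GNLY are NK cell markers and cytotoxic effector genes, and S100A8, S100A9 and S100A12 are granulocyte markers and S100 list members. Of the plasmacytoid dendritic cell markers, IRF7 is also on the interferon list and GZMB on the cytotoxic list. The cycling markers are also on the proliferation list. Granulocyte markers rose in T-like cells of marrow (median 1.89), blood (1.63) and spleen (2.66), B-like cells of marrow (2.12) and spleen (1.90), and NK-like cells of marrow (1.89). NK cell markers rose in T-like cells of marrow, blood and spleen (2.03, 1.57 and 2.41) and in B-like cells of lymph (1.23) and spleen (1.13). B cell markers fell in T-like cells of lymph, blood and spleen (−0.55, −0.77 and −0.77; in blood 0.006 without old replicate 2) and in monocyte/macrophage-like cells of marrow (−1.45) and spleen (−3.66). Monocyte/macrophage markers rose in T-like cells of blood (1.48) and spleen (2.15) and in NK-like cells of spleen (1.04). Platelet markers rose in T-like cells of blood (1.63) and in monocyte/macrophage-like cells of blood (2.27). Plasmacytoid dendritic cell markers rose in 5 of 9 tests, plasma cell markers rose in 3 and fell in 1 of 11, T cell markers rose in 1 and fell in 2 of 10, B precursor markers fell in T-like cells of lymph (−0.94), conventional dendritic cell markers rose in B-like cells of lymph (1.07), and erythroid markers rose in monocyte/macrophage-like cells of marrow (1.26, but −0.71 without old replicate 1). Cycling markers rose in 6 of 11 tests and fell in 1, and the proliferation list rose in 5 of 14 and fell in 1, both falling in monocyte/macrophage-like cells of spleen (−3.07 and −2.27). Without old replicate 1 the median of cycling markers was −0.25 in T-like cells of marrow and −0.54 in those of spleen, where that of proliferation genes was −0.13; without clusters mostly of 1 library these 2 spleen medians were −0.2345 and −0.205. Endothelial, stem cell and stromal markers were called in none of 1, 1 and 2 tests.

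In T-like cells, the spleen had the largest number of age differences at an unadjusted p, with effector genes high and naive genes low in the old animals. CCL5, a chemokine of effector T cells, was at 1584 ± 106 CPM in old and 336 ± 26.1 CPM in young spleen (SD, n = 2; log2 2.24, SE 0.153) and rose when adjusted over the list alone (adjusted p = 0.000896). The killer cell receptor gene KLRD1 (3.20), the granule gene GNLY (2.26), the cytokine gene IFNG (2.59), CCL3 (2.51) and S1PR5 (1.63) also rose there by this adjustment. TCF7, a transcription factor of naive and stem-like T cells, was at 24.6 CPM in old and 69.0 CPM in young spleen (log2 −1.49, adjusted p over the list alone 0.00168). With it fell LEF1 (−1.16), CD28 (−1.22), BACH2 (−1.79) and CCR7 (−0.84). The inhibitory receptor genes LAG3 (2.37) and CD244 (2.23) rose and BTLA fell (−1.89), as did the stress-response gene SESN1 (−0.99), while CDKN2B rose (1.90).

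In T-like cells of blood PLSCR1 was at 30.1 ± 4.66 CPM in old and 1.97 ± 0.493 CPM in young animals (log2 3.95, adjusted p over the list alone 0.00145), and IRF7 (1.42) rose with it. HAVCR2 was measured at 1.37 CPM in old and 0 CPM in young blood T-like cells. In marrow PLSCR1 (3.75), LAG3 (1.40) and SOD2 (0.80) rose. In lymph MX2 (1.93), ISG15 (1.62), the galectin gene LGALS3 (2.02) and the B cell chemoattractant CXCL13 (3.02) rose, and HSPB1 (−2.81), FKBP4 (−1.03), HSPH1 (−0.79) and STIP1 (−0.70) fell. In spleen the granulocyte genes S100A8 (4.36) and S100A9 (4.52) passed over the list alone as well.

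Over all genes tested, edgeR called 0 genes in T-like cells of each tissue. At an unadjusted p under 0.05 there were 756 of 10488 genes in marrow, 1116 of 12242 in lymph, 535 of 12452 in blood and 1728 of 11798 in spleen, and DESeq2, of whose 218 calls in simulated T-like cells of blood 105 were false, called 155, 434, 187 and 1209. Between 33.5 and 48.3% of genes had both old libraries on 1 side of both young ones over the 14 combinations, against 0.333 of genes by chance. Without old replicate 1 edgeR called 551 genes in marrow, 167 in lymph and 1932 in spleen, without old replicate 2 it called 5, 29 and 1695, and without young replicate 2 it called 1 in lymph. Cluster 19 held 46.2% of the spleen T-like cells of old replicate 1 and cluster 2 held 51.3% of those of old replicate 2 and 64.3% of its blood T-like cells, and cluster 15 held 39.8% of its lymph T-like cells. Without clusters that came mostly from 1 library 3 genes were called in marrow, 8 in lymph and 3 in spleen.

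In B-like cells, PLAC8, a small cysteine-rich protein of blood cells, had the largest named difference of marrow, at 114 ± 17.1 CPM in old and 8.81 ± 1.80 CPM in young animals (SD, n = 2; log2 3.72, SE 0.274, edgeR adjusted p = 0.000642). GCA (2.44, 0.0385), CHMP7 (1.85, 0.0385), NTAN1 (1.54, 0.0426) and PLSCR1 (2.71, 0.0489) rose there as well. In lymph ISG15 rose (1.75, adjusted p = 0.0426). In spleen the granzyme gene GZMB was at 68.3 ± 15.4 CPM in old and 8.90 ± 1.35 CPM in young animals (log2 2.93, SE 0.221, adjusted p = 0.0303), and CCL5 rose (2.12). GZMB has close relatives whose reads the counting could split, so its level is uncertain.

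When adjusted over each list alone, interferon genes of B-like cells rose in lymph (IFI27 4.17, MX1 1.49 and XAF1 1.32 among 19 members) and in blood (IFI27 4.85 among 11). Genes of naive B cells fell in lymph: FCER2, the low-affinity IgE receptor, was at 199 CPM in old and 460 CPM in young animals (log2 −1.21, adjusted p over the list alone 0.0038), with IL4R (−1.30), BACH2 (−0.83), TCL1A (−0.82) and CD72 (−0.67). S100A4 (0.95), S100A6 (1.00) and CRIP1 (0.88) rose there. In spleen, besides GZMB, the NK cell genes KLRD1 (3.29), PRF1 (2.79), NKG7 (2.25) and GZMA (2.45) rose, TBX21 fell (−1.68), and TCL1A (0.82), CXCR4 (0.85) and CCR7 (0.94) rose. In marrow S100A8 (2.51), S100A12 (3.39), the inhibitory receptor gene TIGIT (2.10), SOD2 (1.31) and HMGB2 (0.98) rose and FCER2 (−0.87), CD72 (−0.83) and SESN1 (−1.06) fell. TIGIT rose also in blood (1.96).

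edgeR called 8 genes up and 1 down of 9004 in marrow, 7 up and 4 down of 11028 in lymph, 5 up of 11206 in spleen and 0 of 10421 in blood. In blood 523 genes had an unadjusted p under 0.05 and DESeq2 called 41. Without old replicate 1, old replicate 2, young replicate 1 and young replicate 2 in turn, edgeR called 77, 48, 43 and 31 genes in marrow, 89, 5, 116 and 242 in lymph, 29, 15, 29 and 8 in blood, and 161, 41, 29 and 18 in spleen. The marrow values rest on 50 to 768 cells per library, and cluster 10 held most B-like cells of marrow and blood, cluster 5 those of lymph and cluster 9 those of spleen in every animal.

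NK-like cells, those of clusters 11 and 27, differed with age in blood and marrow. In blood APOL2, an apolipoprotein L gene, was at 394 ± 0.831 CPM in old and 81.1 ± 9.68 CPM in young animals (SD, n = 2; log2 2.29, SE 0.186, edgeR adjusted p = 0.0002665), and SLAMF7 (2.85), TNFSF14 (2.63), ABI3 (2.19) and SYTL2 (2.09) rose with it. LEF1 and SOX4, transcription factors of immature lymphocytes, fell by 3.52 and 3.60 on the log2 scale, with TMEM213 (−3.84, adjusted p = 8.45e-05), RTKN2 (−3.785) and IGFBP2 (−4.15). Among members of called lists PLSCR1 (1.61), XAF1 (1.52), CST7 (1.503) and PLEK (1.23) rose and IFI44 (−1.63) and IL7R (−0.87) fell. In marrow PRDM1, a driver of terminal effector differentiation, was at 85.99 ± 4.40 CPM in old and 7.66 ± 2.39 CPM in young animals (log2 3.38, SE 0.391, adjusted p = 0.00595). SLAMF7 (2.65), FCGR3 (2.38) and the granulocyte genes DEFA1B (2.64) and GCA (2.38) rose there too. LEF1 (−4.05), CST6 (−3.21), SOX4 (−2.97), RTKN2 (−2.94), CCR7 (−1.92) and the B cell gene CD79A (−2.35) fell.

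When adjusted over each list alone, IL18 rose in NK-like cells of marrow (2.22), blood (1.905) and spleen (1.48). In blood CX3CR1 (3.68), the fractalkine receptor of mature cytotoxic cells, and IFNG (2.86) rose and the inhibitory receptor gene PDCD1 (−1.145) fell by this adjustment, and in marrow GZMK (2.08) rose and TCF7 (−1.13) and GZMM (−0.73) fell. edgeR called 19 genes up and 9 down of 6661 in marrow, 68 up and 89 down of 8670 in blood, and 1 up of 9795 in spleen, where 912 had an unadjusted p under 0.05 and DESeq2 called 143. The counts without old replicate 1, old replicate 2, young replicate 1 and young replicate 2 in turn were 15, 217, 8 and 70 in marrow, 35, 620, 15 and 147 in blood, and 185, 91, 0 and 0 in spleen. A library had 83 to 239 of these cells in marrow, 88 to 868 in blood and 1130 to 1746 in spleen, and cluster 11 held most of them in every library.

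Cluster 17, which scored as NK-like but stayed unnamed because its leading genes hold more T-like than NK-like markers, was compared in blood. The interferon-induced genes PLSCR1 (2.57) and IRF7 (2.27) and the apolipoprotein L gene APOL6 (2.26) rose there, with NUDT1 (2.43) and DSE (5.14). KIR2DL4 (−2.68), SLC25A6 (−1.63), SGMS1 (−1.45) and PLIN2 (−1.23) fell; KIR2DL4 belongs to a multigene family and its count is uncertain. edgeR called 25 genes up and 7 down of 8405, and 9, 111, 101 and 113 genes without old replicate 1, old replicate 2, young replicate 1 and young replicate 2 in turn. The libraries had 86 to 1360 cells of this cluster.

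In monocyte/macrophage-like cells of blood, PLAC8 was again the gene with the largest named difference, at 377 ± 75.2 CPM in old and 25.1 ± 2.31 CPM in young animals (SD, n = 2; log2 3.90, SE 0.241, edgeR adjusted p = 2.08e-05). The succinate receptor gene SUCNR1 (3.28, 0.0327) and PLAAT4 (2.69, 0.00472) rose, and so did interferon and inflammatory genes, namely PLSCR1 (2.04), OASL (1.89), IER3 (2.45) and the adhesion gene ICAM1 (1.97). The platelet genes PF4 (2.53, 0.00342), PPBP (2.27) and NRGN (2.35, 0.0153) rose in the same cells. The antimicrobial gene CAMP (−1.96, 0.0418), the sorting receptor gene SORL1 (−1.86, 0.00159), the lipid-antigen presenting gene CD1C (−1.43, 0.0153), SPECC1 (−1.25) and IFT57 (−1.14) fell.

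Among the genes that fell in this class in spleen were B cell genes: MS4A1 was at 29.6 ± 12.9 CPM in old and 579 ± 42.8 CPM in young animals (log2 −4.32, adjusted p = 0.0126), with CR2 (−4.07), CD79B (−4.04), FCMR (−3.87), PAX5 (−5.27) and BLK (−5.19), while GBP7 rose (1.86). All 12 measured B cell markers fell there when adjusted over the list alone, and the B-like share of spleen cells was 18.1% in old and 33.9% in young animals. By the same adjustment SOD2 rose in spleen, at 1482 ± 347 CPM in old and 362 ± 81.8 CPM in young animals (log2 2.03, adjusted p over the list alone 0.00317), with IL1B (1.38) and IL1RN (2.06). In marrow GZMB (2.30) and PLSCR1 (1.27) rose and FKBP4 (−1.38) and HSPA1B (−1.48) fell by it.

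edgeR called 42 genes up and 13 down of 9606 in blood, 3 up and 25 down of 7861 in spleen, and 0 of 10338 in marrow, where 615 had an unadjusted p under 0.05 and DESeq2 called 121. The counts without old replicate 1, old replicate 2, young replicate 1 and young replicate 2 in turn were 168, 338, 13 and 8 in blood, 243, 71, 0 and 0 in spleen, and 0, 0, 4 and 14 in marrow, and in the spleen of young replicate 2 cluster 30 held 80.7% of these cells where cluster 12 led in the other animals.

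Whether the age difference itself varied between tissues was tested with interaction terms. In B-like cells PLAC8 differed by age by 3.72 in marrow, 3.04 in blood and 1.30 in lymph on the log2 scale and by −0.09 in spleen (edgeR adjusted p of the difference between tissues 3.63e-05). The mitosis gene CENPF was higher with age in marrow (0.94) and lymph (0.85) and lower in blood (−0.43) and spleen (−0.80), and TNFRSF13B, a receptor for B cell survival factors, stood at 0.64 in lymph and −0.73 in spleen. In NK-like cells TIGIT stood at 1.38 in marrow, 2.57 in blood and 0.77 in spleen (adjusted p of the difference between tissues 2.95e-08), SYTL2 at 2.18, 2.09 and 0.30, FOS at 0.69, −1.09 and 0.72, and ID3 at −1.845, −2.18 and −0.71. In monocyte/macrophage-like cells the B cell genes BANK1 (−2.62), CD22 (−1.97), SPIB (−2.23) and BLNK (−2.80) and TCF4 (−2.10) were lower with age in spleen, and IL1B was higher (1.38). In T-like cells PTPN13 (−2.34), PHACTR2 (−1.47) and IRAK3 (−1.63) were lower with age in spleen. These genes were chosen after their values were seen. In all, 3 genes were called in T-like, 5 in B-like, 58 in NK-like and 26 in monocyte/macrophage-like cells, and without the animal as a block 0, 1, 0 and 1. Without old replicate 1, old replicate 2, young replicate 1 and young replicate 2 in turn, the counts were 148, 422, 0 and 0 in T-like, 76, 17, 31 and 40 in B-like, 17, 100, 13 and 32 in NK-like, and 141, 33, 120 and 49 in monocyte/macrophage-like cells.

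Between tissues, T-like cells of lymph differed from those of blood in activation genes. FOS, an immediate early transcription factor gene, was at 1470 ± 510 CPM in lymph and 9.34 ± 4.53 CPM in blood (SD, n = 4; log2 7.30, SE 0.522, edgeR adjusted p = 0.000462). FOSB (7.18), NR4A2 (6.20), JUN (5.14) and RGS1 (5.86), a regulator of chemokine signalling, rose too. The migration-related genes KLF3 (−2.30) and AHNAK (−2.28) fell, with SPINK2 (−2.34), GOLIM4 (−2.31) and the haemoglobin gene HBA (−5.35), which is 1 of several near-identical copies. Of the immediate early list 21 of 25 members rose (median 2.93), of the NF-kB list 12 of 20, of the checkpoint list 7 of 15 and of the heat shock list 9 of 20, while 6 of 13 S100 list members fell and 5 of 36 interferon genes fell and 1 rose. Of the genes of other cells, 3 of 7 plasma cell markers (median 2.06), 3 of 6 stromal markers (4.31), 2 of 11 B cell markers, 5 of 8 naive B cell genes and 5 of 11 cycling markers rose, 4 of 9 erythroid markers fell and 1 rose, and 3 of 14 monocyte/macrophage markers fell. Collagenase digestion is described for lymph only, so tissue and digestion cannot be told apart in these differences.

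T-like cells of marrow differed from those of blood in granulocyte genes, with LTF at 109 ± 70.3 CPM and 0.116 CPM (log2 9.55), CAMP (7.41) and S100A8 (5.11) up and 11 of 15 granulocyte markers up (median 6.08). Granulocyte-like cells were 52.7% of marrow cells. RTD1A, a defensin gene, had 3944 UMIs in marrow T-like cells and 1 in blood, a pooled ratio of 18550 with a counting interval of 3327 to 732800. DEFA1B had 3362 UMIs against 1; both belong to a multigene family and are uncertain. edgeR called 753 genes up and 427 down of 12532 in lymph, 59 up of 11671 in marrow and 1 up of 12189 in spleen, where 1138 had an unadjusted p under 0.05 and DESeq2 called 431. With the animal as a block the counts were 3085 in lymph (1629 up and 1456 down), 417 in marrow (258 up and 159 down) and 80 in spleen (67 up and 13 down), of which 1167, 55 and 1 were shared with the fit without it. Without young replicate 1 the counts were 279, 16 and 0, without young replicate 2 they were 301, 18 and 0, and without old replicate 1 marrow had 27 and spleen 23, while spleen had 79 without old replicate 2.

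B-like cells of lymph also had more activation genes than those of blood. Here too collagenase digestion applies to lymph only, so tissue and digestion cannot be told apart. CD69, an early activation antigen, was at 1123 ± 299 CPM in lymph and 30.4 ± 18.2 CPM in blood (SD, n = 4; log2 5.44, SE 0.412, edgeR adjusted p = 0.000137), with AREG (6.47), RGS1 (6.24), FOSB (5.72) and FOS (4.94). The nuclear lamin gene LMNA (−4.76), the kinase gene FGR (−4.37), and HBB (−10.46) and HBA (−5.89) fell. The platelet gene PPBP had 1 UMI in lymph and 2414 in blood, a ratio of blood over lymph of 4064 with a counting interval of 729 to 160600. In lymph 22 of 25 immediate early genes rose and 1 fell (median 2.34), 7 of 17 NF-kB genes, 9 of 20 heat shock genes, 41 of 78 ribosomal protein genes and 5 of 9 naive B cell genes rose, and 11 of 13 S100 list members and 8 of 14 age-associated B cell genes fell. There 4 of 8 plasma cell, 3 of 11 cycling and 2 of 10 T cell markers rose, and 4 of 10 monocyte/macrophage markers fell and 1 rose. In spleen the complement receptor gene CR2 of marginal zone and follicular B cells was at 615 ± 163 CPM against 39.0 ± 20.4 CPM in blood (log2 4.13), and ITGA1 (5.84), CCR6 (2.50) and SEMA7A (2.35) rose, while AHNAK (−2.59), LMNA (−2.51), CRIP1 (−2.12), KLF6 (−2.09) and PPBP (−4.12) fell. TAC3, a tachykinin gene, had 5126 UMIs in spleen and 2 in blood, a ratio of 1392 with a counting interval of 385 to 11490. In spleen 52 of 79 ribosomal protein genes and 8 of 15 NF-kB genes rose, 4 of 22 immediate early genes rose and 5 fell, and 7 of 13 S100 list members, 6 of 14 age-associated B cell genes and 5 of 15 senescence genes fell, while 4 of 13 monocyte/macrophage markers rose and 1 fell and 3 of 10 T cell markers fell and 1 rose. B-like cells of marrow showed granulocyte genes again, with CAMP (7.41) and S100A8 (5.50) up, 9 of 11 granulocyte markers up (median 6.88), and LTF at 561 UMIs against 3 (ratio 651, counting interval 222 to 3166) and DEFA1B at 620 against 1.

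edgeR called 880 genes up and 842 down of 10929 in B-like cells of lymph, 597 up and 595 down of 11108 in spleen, and 19 up of 9571 in marrow. With the animal as a block the counts were 2832 (1477 up and 1355 down), 2608 (1273 up and 1335 down) and 87 (71 up and 16 down), of which 1710, 1189 and 19 were shared with the fit without it. Without young replicate 1 lymph had 833 and spleen 408, and without young replicate 2 they had 949 and 361. Cluster 5 held most B-like cells of lymph, cluster 9 those of spleen and cluster 10 those of blood and marrow.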

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

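The tests of whether 1 animal carries the interferon difference, the measure of free RNA from 3 marker genes and the other splits of the libraries were chosen after the results had been seen. A value far from the others is 1 whose gap to the nearest of 4 animals exceeds what chance gives in about 1 of 20 groups.

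In 14 combinations of cell class and tissue, genes of the type I interferon response were higher in the 2 old than in the 2 young animals. That 1 animal carries this is argued against in T-like, B-like and NK-like cells. There both old libraries lay above both young ones on the list mean in every tissue tested. It stays open in monocyte/macrophage-like cells, where old replicate 1 was highest in marrow, blood and spleen (5.48, 6.44 and 6.75). Old replicate 2 stood at 4.91, 5.66 and 6.07. Young replicate 1 stood at 4.72, 5.27 and 5.42 and young replicate 2 at 5.13, 5.60 and 6.68. With the preset correlation the list stayed called in at least 11 of the 14 whichever animal was left out. Those calls do not measure the spread between animals, and no call of the list held with an estimated correlation (camera, lowest adjusted p = 0.449). RNA from other cells in the droplets stays open, because the rise was over 3 times what such RNA could bring in 1 of 8 T-like and B-like combinations (B-like cells of lymph, 3.98 times); with the measure from 3 marker genes, the ratio was 4.54, 5.37 and 8.51 in T-like cells of marrow, lymph and spleen and 5.21 in B-like cells of lymph, and below 3 in the other 4. A difference between these animals other than age cannot be told apart from age, because 4 animals allow only 3 pairings, and in 2 of the 14 combinations another pairing gave as large a difference. Age itself stays among the open explanations, untested.

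Among class shares, 10 of 42 groups of 4 animals held a value far from the others. All 10 lay above the others, and 8 of them were in an old animal. The rule was applied to untransformed shares, which cannot be negative, and the shares of a library depend on each other. The 42 groups are therefore not independent, and the number and side of these values are no test of age. Old replicate 1 had 2.85% plasma cell-like cells in marrow (next 1.03%) and 3.29% in spleen (next 0.651%), 6.03% cycling-like cells in lymph (next 1.86%) and 5.34% in spleen (next 1.39%), and 4.07% platelet-like cells in blood (next 1.20%). Old replicate 2 had 71.95% granulocyte-like cells in marrow (next 47.68%) and 1.03% in spleen (next 0.156%), and 1.03% cycling-like cells in blood (next 0.256%). Young replicate 1 had 0.131% granulocyte-like cells in lymph (next 0.0248%), and young replicate 2 had 2.38% stromal-like cells in lymph (next 0.578%).

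Among the genes named between tissues, 5 of 72 groups held such a value, and another 6 groups with at most 3 UMIs in all were not tested, since 1 library with a UMI among 3 at 0 always stands apart. HBA was at 77.25 CPM in T-like cells of lymph in old replicate 2, where the next value was 8.64 CPM. In B-like cells, CAMP was at 536 CPM in marrow of old replicate 1 (next 160 CPM), AREG at 173 CPM in lymph of young replicate 1 (next 67.2 CPM), ITGA1 at 8.41 CPM in blood of old replicate 2 (next 1.44 CPM), and CRIP1 at 454.5 CPM in spleen of young replicate 1 (next 358.8 CPM).

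The age difference itself differed between tissues, by edgeR's interaction test, for 3 genes in T-like, 5 in B-like, 58 in NK-like and 26 in monocyte/macrophage-like cells. Adjusted p was 3.63e-05 for PLAC8, 0.00206 for CENPF and 0.04865 for TNFRSF13B in B-like cells, and 0.000228 for BANK1 and 0.00356 for TCF4 and SEPTIN6 in monocyte/macrophage-like cells. It was 2.95e-08 for TIGIT, 1.33e-05 for SYTL2 and 2.37e-05 for FOS in NK-like cells, and 0.0499 for IRAK3, PHACTR2 and PTPN13 in T-like cells. The counts moved without single animals, from 0 without young replicate 1 to 422 without old replicate 2 in T-like cells, from 17 without old replicate 2 to 76 without old replicate 1 in B-like cells, from 13 without young replicate 1 to 100 without old replicate 2 in NK-like cells, and from 33 without old replicate 2 to 141 without old replicate 1 in monocyte/macrophage-like cells.

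In 2 classes all old animals lay on opposite sides of the young ones in different tissues, and these differences were not tested. The log2 difference of the dendritic-like share was 0.31 in spleen and −0.92 in marrow, and that of the platelet-like share was 1.95 in blood and −0.69 in marrow.

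For the tissue comparisons, each count of called genes was set against all 35 ways to split the same 8 libraries into groups of 4, which ignores that each animal gave both libraries. In T-like cells of lymph, 1 of the 35 splits, the real one, gave 1180 genes and the highest other gave 11. The real split also stood alone in B-like cells of lymph (1722 against 5) and of spleen (1192 against 46). Because the 35 splits ignore the shared animals, these ranks do not exclude chance. Both the 46 and the 84 given below come from the split of old from young animals. That split equals the age covariate of the other fits, so it was fitted without the covariate. Its counts are therefore not like the others. In the other 3 comparisons the real split did not stand alone, and chance stays open there as well. With the real one included, 3 splits gave as many as 59 genes in T-like cells of marrow (highest 889). As many as 1 came from 4 splits in T-like cells of spleen (highest 84), and as many as 19 from 4 splits in B-like cells of marrow (highest 178). The splits that gave more followed animals: replicate 1 from replicate 2 animals for the 889, old from young for the 84, and young replicate 1 with old replicate 2 from the other pair for the 178. They part no animal's 2 libraries, whereas the real split parts those of all 4. Whether lasting differences between animals or, for the split of old from young, age lies behind them cannot be told apart. Only 8 splits part the libraries of every animal, too few for a share under 0.05 in any of the 6 comparisons. With the animal as a block the real one gave 417, 3085 and 80 genes in T-like cells of marrow, lymph and spleen, where the highest other gave 0 in each, and 87, 2832 and 2608 in B-like cells, where the highest other gave 15, 7 and 8.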

How the results depend on the processing

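Alternatives chosen after seeing the data were leaving out clusters that came mostly from 1 library, testing cluster 11 alone, counting cluster 17 as NK-like, naming sub-clusters by a rule of 1 marker, and leaving out animals in the interaction test and for clusters by number. The stricter cell filter was not run for B-like cells of marrow, where too few cells remained. No paired analysis was possible because each animal has 1 age, for old against young; between tissues the animal pairs the libraries. Leaving out an animal leaves 1 library in its age group, which is then assumed to vary like the other group. Median depth was lowest in marrow, and thinning to equal depth moved counts in marrow, blood and spleen. Of the named genes, 656 of 856 results kept their direction and side of the threshold between ages, 200 lost the call and none turned, and between tissues 393 of 429 kept it and 36 lost it. Of 64 genes named between ages, 28 kept the call with doublet-like cells kept, 24 with all tissues in 1 fit, and 22 to 61 without single animals. List tests were kept in 1447 of 1744, lost in 280 and turned in 17. For classes and T subsets 174 of 211 results kept their call, 27 lost and 9 gained it, and 1 turned; the T subset counts here include the naive, CD4 and cytotoxic T-like names, which the report does not compare by name. Where values below moved, the cause was not tested, except that leaving out an animal or a filter also changes the samples or genes tested.

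DESeq2 called over 1.5 times as many genes between ages in 13 comparisons: 155, 434, 187 and 1209 in T-like cells of marrow, lymph, blood and spleen, 53, 190, 41 and 390 in B-like cells, 54 and 143 in NK-like cells of marrow and spleen, and 121, 186 and 198 in monocyte/macrophage-like cells of marrow, blood and spleen. Against blood it called 151, 2441 and 431 in T-like cells of marrow, lymph and spleen and 36, 2661 and 2161 in B-like cells. With no expression filter edgeR called 97, 20, 1 and 21 genes in T-like cells of marrow, lymph, blood and spleen, 128, 161, 211 and 118 in B-like cells, 170, 521 and 155 in NK-like cells of marrow, blood and spleen, and 97, 328 and 512 in monocyte/macrophage-like cells. Without the filter the interaction counts were 9 in T-like, 33 in B-like and 587 in monocyte/macrophage-like cells, and against blood there were 113 genes in B-like cells of marrow and 3 in T-like cells of spleen.

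With all tissues in 1 fit, 4 and 61 genes were called in T-like cells of blood and spleen, 4, 18, 6 and 13 in B-like cells of marrow, lymph, blood and spleen, 11, 91 and 18 in NK-like cells of marrow, blood and spleen, and 2, 17 and 120 in monocyte/macrophage-like cells. With doublet-like cells kept, B-like cells had 5 in lymph and 1 in spleen, NK-like cells 11 in marrow, 60 in blood and 6 in spleen, monocyte/macrophage-like cells 21 in blood and 0 in spleen, and the interaction called 1 in T-like, 3 in B-like and 25 in NK-like cells; against blood, marrow had 126 in T-like and 84 in B-like cells. After thinning to equal depth, B-like cells had 5 in marrow and 8 in spleen and NK-like cells 43 in blood. At resolution 2, B-like cells of lymph had 7, monocyte/macrophage-like cells of marrow 1 and NK-like cells 45 in marrow and 3 in spleen. Cluster 11 alone gave 58 genes in marrow and 0 in spleen, and with cluster 17 counted as NK-like blood had 70. Without clusters mostly of 1 library, T-like cells had 3 in marrow, 8 in lymph and 3 in spleen, and 78 in spleen against blood.

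With the replicate block, tissue against blood gave 417, 3085 and 80 genes in T-like cells of marrow, lymph and spleen and 87, 2832 and 2608 in B-like cells. The block ended the call of 2 of 39 named genes and 1 of 26 class results. With no replicate block the interaction called 0 in T-like, 1 in B-like, 0 in NK-like and 1 in monocyte/macrophage-like cells. The list tests, with 53 calls in T-like, 34 in B-like, 25 in NK-like and 33 in monocyte/macrophage-like cells, fell to 0 in each with the estimated correlation. TMM factors on cell numbers gave 1 T subset call in marrow and 0 in lymph, and the 1-marker rule 1 in blood.

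Over the 4 animals left out in turn, counts between ages ranged from 0 to 551, 0 to 167, 0 to 0 and 0 to 1932 in T-like cells of marrow, lymph, blood and spleen, 31 to 77, 5 to 242, 8 to 29 and 18 to 161 in B-like cells, 8 to 217, 15 to 620 and 0 to 185 in NK-like cells of marrow, blood and spleen, and 0 to 14, 8 to 338 and 0 to 243 in monocyte/macrophage-like cells. Against blood they ranged from 16 to 60, 279 to 1100 and 0 to 79 in T-like cells of marrow, lymph and spleen and 15 to 24, 833 to 1887 and 361 to 1528 in B-like cells. Interaction counts ranged from 0 to 422, 17 to 76, 13 to 100 and 33 to 141 in T-like, B-like, NK-like and monocyte/macrophage-like cells, and list calls from 39 to 63, 33 to 38, 20 to 29 and 18 to 29. Class calls between ages ranged from 0 to 6 in marrow, 0 to 2 in spleen and 0 to 0 in lymph and blood, T subset calls from 0 to 5 in marrow, 0 to 3 in spleen and 0 to 1 in lymph and blood, and class calls against blood from 5 to 9 in marrow, 8 to 10 in lymph and 3 to 6 in spleen.

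The GZMK T-like share of spleen turned to 0.0308 (log2) with TMM factors, and with cluster 17 counted as NK-like the median of ribosomal protein genes in NK-like cells of blood turned to 0.0194. Without clusters mostly of 1 library, medians turned in T-like cells for ribosomal protein genes of blood (0.0671) and spleen (0.144) and, in spleen, for cycling markers (−0.2345) and proliferation genes (−0.205). Without single animals, medians of ribosomal protein genes ranged from −0.271 (without old replicate 2) to 0.0298 (without old replicate 1) in B-like cells of lymph, from −0.813 (without old replicate 1) to 0.275 (without old replicate 2) in T-like cells of blood, and from −0.702 to 0.0607 (the same 2 animals) in T-like cells of marrow. Without old replicate 1 and old replicate 2 they were −2.25 and 0.006 for B cell markers and −1.155 and 0.0396 for naive and central memory genes in T-like cells of blood. In the same order they were −0.251 and 0.758 for cycling markers in T-like cells of marrow, −0.538 and 2.125 for cycling markers and −0.131 and 1.83 for proliferation genes in T-like cells of spleen, and −0.71 and 2.03 for erythroid markers in monocyte/macrophage-like cells of marrow. Without young replicate 1 and young replicate 2 they were −0.02805 (with the test's direction turned) and −0.723 for naive and central memory genes in B-like cells of lymph, −0.00361 and 0.215 for oxidative phosphorylation genes in monocyte/macrophage-like cells of blood, and −0.294 and 1.08 for interferon genes in monocyte/macrophage-like cells of spleen.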

Other observations

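The genes named in this part were chosen after their values were seen. So were the tests of free RNA in B-like cells and with 3 marker genes, of the alpha segment in 4 tissues, and of the segment pairs in both directions.

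Outside the fixed lists, some genes were higher in both old animals than in both young ones in all 14 combinations of class and tissue. The apolipoprotein L gene APOL2 had a mean log2 difference of 1.97, the guanylate-binding protein genes GBP3 and GBP7 of 1.38 and 0.93, and the cytidine deaminase gene APOBEC3D of 1.26. The proteasome gene PSME2 (0.89), the MHC class I gene Mamu-B (0.97), which belongs to a multigene family and is uncertain, and NLRC5 (0.71), a regulator of MHC class I genes, were higher as well, with WARS1 (1.32) and UBE2L6 (0.86). ARGLU1 (−0.36), RBM39 (−0.33) and PPIL4 (−0.59) were lower in all 14. These genes are on no fixed list and were not tested as a group. In 3 tissues each of B-like cells, edgeR called ENSMMUG00000053906 and ENSMMUG00000049785, which have no symbol in the files, and the latter, also called in 3 tissues of NK-like cells, had a mean log2 difference of 4.74.

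Of 6133 genes measured in all 14 combinations, 27 parted the 2 old from the 2 young animals in every one, an arrangement chance gives for 0.333 of genes in a single combination, 22 of them higher in old animals, and 2 of these 22 are on the interferon list, IRF9 among them. The other pairings of the animals parted 5 genes each, a number between the bounds set beforehand, so lasting differences between the animals, such as inherited variants, may contribute and cannot be told apart from age. In T-like cells of spleen, 26 of the 27 genes were above 3 times the level that free RNA could bring. The same held in B-like cells of lymph, blood and spleen. This argues against free RNA as the main source of the level of these genes there. The difference between ages was not weighed in this way, so free RNA stays open as a source of it. For the level, free RNA stays open in T-like cells of marrow, lymph and blood, where 9, 23 and 2 were above that bound (27 in each with the measure from 3 marker genes), and in B-like cells of marrow (22). The combinations share animals and free RNA, so they are not independent, the pattern overlaps with the interferon genes, and age was not tested apart from the animal.

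In T-like cells of old replicate 2 the receptor alpha chain segment TRAV29DV5 took 56.5% of alpha segment UMIs in blood (exact 95% interval 54.9 to 58.2%), 42.1% in marrow, 22.6% in lymph and 41.8% in spleen, against 3.32 to 13.0% in the other animals. An artifact of 1 library is argued against, since the segment was over 2 times as frequent as in each other animal, with exact intervals apart, in 4 of 4 tissues, and so was the beta segment TRBV27 (11.64 to 20.03% against 1.12 to 6.80%). In sub-clusters 2, 3, 11, 12, 14 and 21 together, which scored as cytotoxic T-like, the beta segment TRBV11-1 took at least 73.41% of beta segment UMIs in blood, lymph and spleen of this animal. This is what 1 expanded clone seen in several tissues would need, but the segment also led in 4 of 4 libraries of other animals that could be compared (46.6 to 90.3%). Among all T-like cells it took 63.17 to 74.31% in this animal and 22.95 to 80.43% in the others. It was over 2 times as frequent as in each other animal in 0 of 4 tissues. Since the segment is frequent in T-like cells of every animal, its share cannot decide for or against 1 expanded clone, which stays open. Separate clones, each with its own pair of segments, may contribute and cannot be told apart from this: in blood TRAV29DV5 was seen with TRBV11-1 in 551 cells and with TRBV27 in 163, and TRAV12-3 in 64 and 1 (odds ratio 0.0528, exact 95% interval 0.0013 to 0.311), while the intervals of lymph (0 to 2.57) and spleen (0.0046 to 1.23) include 1 and marrow was at 2.2 with 18 cells, and the bound set beforehand, an odds ratio under 3, was wrong, since pairing in the other direction also gives such a value. Whether age has a part was not tested.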
